A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

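RNA-seq was carried out on 18 libraries of the budding yeast strain BY4742: wild type (WT), a strain without SET2 (set2Δ) and a strain without BRE1 (bre1Δ), each at day 1 and at day 4 of chronological aging, with 3 replicates in each of the 6 groups. The deposited tables give read counts per gene and FPKM for each library, per the file headers. The authors state that reads were checked with FastQC 0.11.8, trimmed with cutadapt 2.6, aligned to the sacCer3 genome with STAR 2.7.0b and counted with HTSeq 2.0.2, and that expression was compared in R 4.2.0 with DESeq2 1.36.0. The strand setting of HTSeq, the annotation it used and whether the replicates were separate cultures are not stated. The FPKM values followed from the counts, the total of each column and a gene length, and that length lay within 2% of the gene's span in the reference annotation for 99.7% of the 6031 genes that have both lengths. Raw counts were used throughout, and FPKM served in alternatives only.

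Each table holds 6837 identifiers. Of these, 5926 matched a locus tag of the R64 reference annotation, 99 a symbol and 6 a synonym, while 806 did not match and were kept under the name the tables give. A further 4 identifiers whose names had been emptied were left out. ARG5,6 and DUR1,2 stand in the tables under other spellings and were not matched to the gene lists. Library totals ranged from 8038470 to 29514490 counts. A level of 3 counts per library, the largest true level that an observed count of 0 allows at 95% confidence, was used as the floor for a fold against a group with 0 counts in all libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

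Genes were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr on the 6 groups (6320 genes tested, 517 not), TMM scaling, 1 model with a mean for each of the 6 groups, and quasi-likelihood F tests, which are two-sided. The common dispersion was 0.00387, a biological coefficient of variation of 6.22%. P values were adjusted by Benjamini-Hochberg over all genes tested in each comparison, with a threshold of 0.05, and changes of at least 2-fold were also counted. The 9 comparisons are day 4 against day 1 in each strain, each deletion against WT at each day, and the difference between the day effect of each deletion and that of WT. Log2 fold changes are given with their standard error from the fit (±), and each group holds 3 libraries. Normalised read counts are in CPM after TMM scaling, given as mean ± SD of 3 libraries.

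Before the data were examined, 41 gene lists, the 9 comparisons, the rule for naming genes and most of the alternatives were fixed. The lists cover ribosomes, mitochondria, carbon and lipid metabolism, stress, protein turnover, nutrient uptake and signalling, chromatin, cell wall, cell cycle, mating and chromosome ends, and most of their genes were assigned by general knowledge of yeast biology. Of the lists, 39 had at least 5 tested members and were compared with all other genes by camera (limma 3.58.1, preset correlation of 0.01), with Benjamini-Hochberg adjustment over 351 tests. For each list the members past the threshold over all genes are counted, and beside them those past it when adjusted over the list alone. Camera with a correlation estimated from the data and fry were run as alternatives.

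The genes named are those the rule selected, apart from 8 other RNAs without a poly(A) tail that a test in the closing part needs. They are the deleted genes with their neighbours, the auxotrophic markers and the mating genes. To these come the 8 genes with the largest rise and the 8 with the largest fall in each of the 9 comparisons (past the threshold, at least 20 CPM in the highest group and, in the 7 pairwise ones, all 3 libraries of one group above all 3 of the other, an order that chance gives in 10% of 3 against 3), up to 4 members of each list with the smallest p values, any member of a list of up to 15 genes, and genes that the deletions changed in opposite directions at day 4.

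The pipeline was tested on simulated counts with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among 6239. For 3 libraries against 3, edgeR recovered 100%, 98.5% and 100% of them, and 9 of its 208 calls were false. For the difference between day effects it recovered 82.1%, 97% and 100%, and 5 of 191 calls were false. DESeq2 1.42.0 made 13 false calls among 211 in the first of these comparisons. Camera called the 1 list that was shifted and 0 of 38 lists that were not. Only these few genes were changed, in equal numbers up and down, whereas most genes tested passed the threshold in the data. The rates therefore hold for few and balanced changes, and they were not tested for changes as wide as those found here.

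Alternatives were DESeq2, limma on log2 FPKM with pseudocounts of 1 and 0.1, scaling by library size only, by upper quartile and by median of ratios, scaling without the cytosolic ribosomal protein and mitochondrial genome genes, no filter beyond a count above 0, a filter of 10 CPM in 3 libraries, a fit on the libraries of the compared groups only, the replicate number as a block, and leaving out each library in turn. After the data had been examined, 3 alternatives were added: protein-coding genes only, removal of each library's trend with gene length, and the replicate number as a block on the 6 libraries of WT and bre1Δ at day 1. In those 2 groups the deviations from the group means of equal replicate numbers correlated at 0.129, 0.137 and 0.129. The numbers may thus pair these libraries, though the labels name no shared culture or batch. These groups were picked among all pairs of groups after the values were seen, so chance is not excluded. For set2Δ at day 1 and day 4 the values were 0.274, 0.048 and 0.135. In no other 2 groups were all 3 pairs over 0.1.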

Results

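Gene expression was measured by RNA-seq of polyadenylated RNA, per the labels, in WT, set2Δ and bre1Δ cells of the yeast strain BY4742 at day 1 and day 4 of chronological aging, the survival of cells in a culture that has stopped dividing. SET2 encodes the methyltransferase of histone H3 lysine K36, and BRE1 encodes a ubiquitin ligase of histone H2B. Each of the 6 groups had 3 libraries. Library totals were 14405784 to 21558268 counts in WT at day 1, 23158487 to 25763314 in WT at day 4, 16083744 to 18527701 in set2Δ at day 1, 8038470 to 15752126 in set2Δ at day 4, 14117059 to 23335510 in bre1Δ at day 1 and 12500920 to 29514490 in bre1Δ at day 4. Values after gene names are log2 fold changes ± SE from edgeR with 3 libraries per group. Every gene said to be higher or lower was past the adjusted p threshold of edgeR in that comparison. Positions are in the R64 reference, of the sacCer3 build the authors used.

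The deleted genes had few or no reads in the strains named for them. Levels in this paragraph are reads relative to library totals, without TMM scaling, while log2 fold changes are with it. SET2 (YJL168C, chromosome X, 102227 to 104428) had 20 reads in the 3 set2Δ libraries of day 1, a level 50.4-fold lower than in WT (95% counting interval 32.5 to 82.9), and 15 reads in those of day 4, 59.9-fold lower (36.2 to 107). BRE1 (YDL074C, chromosome IV, 324047 to 326149) had 0 reads in bre1Δ at day 1, at least 368-fold lower than in WT when 3 counts are assumed in each library, and 2 reads at day 4, 2980-fold lower (825 to 24600). Next to SET2, ERG20 was lower in set2Δ at day 1 (-0.87 ± 0.05) and at day 4 (-0.42 ± 0.05), and ASG7 was lower at day 4 (-1.13 ± 0.32) and not past the threshold at day 1 (-0.24, adjusted p = 0.414). Next to BRE1, AHK1 was higher in bre1Δ at day 1 (0.85 ± 0.07) and day 4 (0.86 ± 0.07), and higher still in set2Δ (1.15 and 1.53). The snoRNA gene SNR63 on the other side of BRE1 was higher in bre1Δ at day 1 (0.55 ± 0.24, adjusted p = 0.0475) and not past the threshold at day 4 (-0.13, adjusted p = 0.58). The call of SNR63 at day 1 rests on single libraries: its adjusted p was 0.165 and 0.0653 without replicate 1 or 3 of WT, and 0.114 and 0.124 without replicate 1 or 2 of bre1Δ. With the replicate number as a block it was 0.0576 over all 18 libraries, and with that block on the 6 libraries compared the call was kept. URA3, LEU2 and LYS2, which BY4742 lacks, had at most 11 counts in any library. HIS3, of which the allele in this strain keeps a part, had 16.6 to 66.8 CPM of library totals. The alpha-specific genes MF(ALPHA)1 and SAG1 were read in every library, and the a-specific genes STE2 and STE6 were read too, at 10.1 to 56.0 CPM of library totals.

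**Figure D1:**
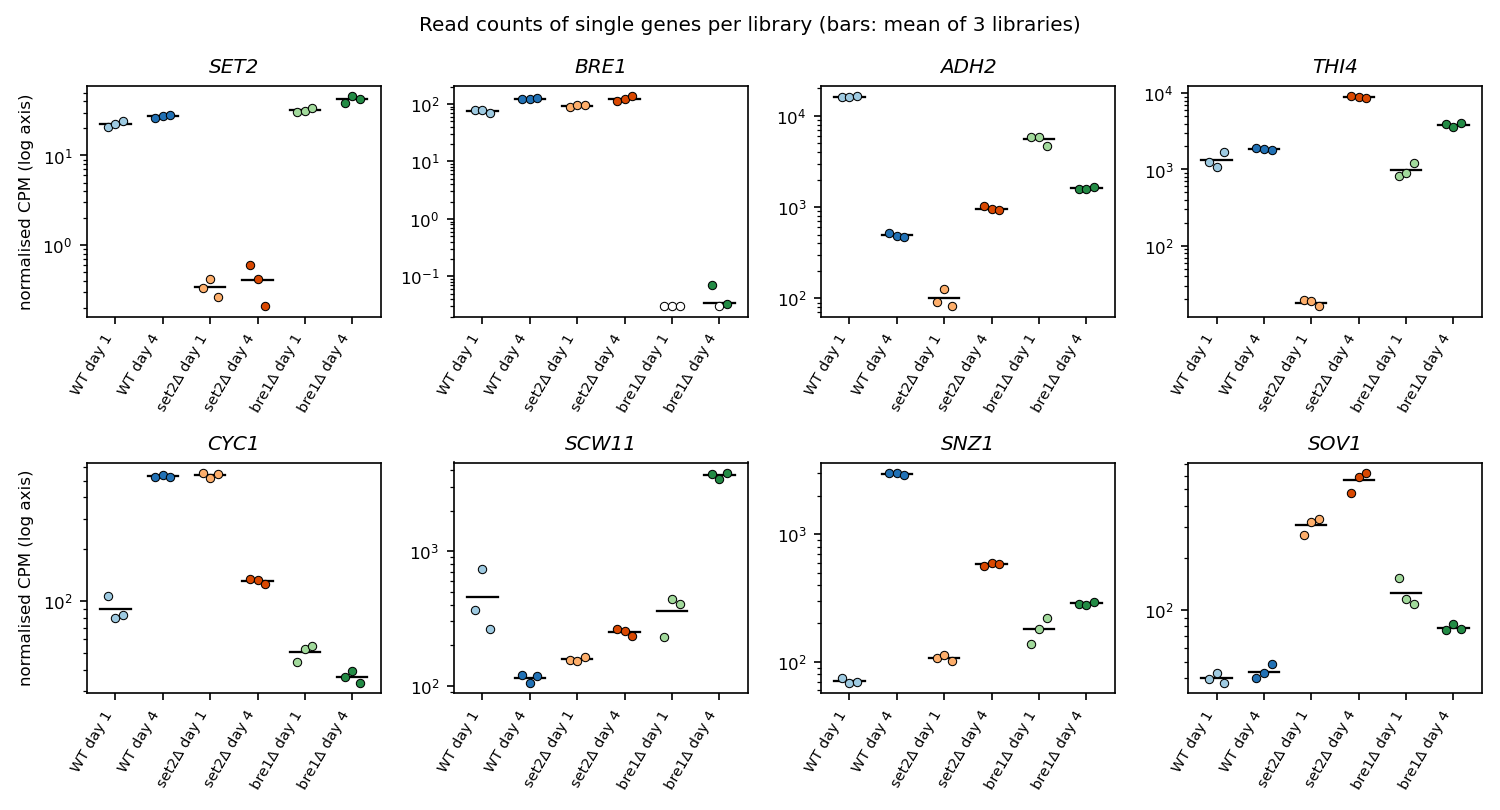
Normalised read counts in CPM (log axis) of 8 genes in the 18 libraries by group, with each point a library, each bar the mean of 3 libraries, and open circles at the bottom marking 0 reads. SET2 and BRE1 lie at or near 0 in the strains that lack them, and ADH2 falls from a mean of 16200 CPM in WT at day 1 to 99.9 CPM in set2Δ at day 1.

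The largest share of the variance between libraries, 41.5% on the first principal component of log2 CPM, was followed by 19.7% and 17.2% on the next components. Replicates of a group lay close together: Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.993 or higher in every pair. Counting error alone would give a chi-square of about 1 per gene between replicates. The pairs gave 1.53 (replicates 1 and 3 of bre1Δ at day 4) to 42.2 (WT at day 1). In WT at day 1 daughter-cell genes such as CTS1 (2210 ± 913 CPM) differed between replicates. In bre1Δ at day 4 the pairs with replicate 2 gave 10.6 and 15.08, so replicates 1 and 3 lay nearer to counting error. Whether replicates were separate cultures is not stated. The p values may therefore not measure the spread between cultures. Cytosolic ribosomal protein genes took 2.07% to 2.91% of the counts in the libraries of WT and of set2Δ at day 1, 4.28% to 4.42% in set2Δ at day 4, 4.93% to 5.35% in bre1Δ at day 1 and 8.20% to 8.37% in bre1Δ at day 4. TMM factors were 0.857 to 0.892 in WT and 1.033 to 1.139 in the deletions. Scaling by library size only moves the median log2 fold change of all genes from -0.01 to 0.35 for set2Δ against WT at day 1, and all changes below are relative to TMM scaling.

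**Figure D2:**
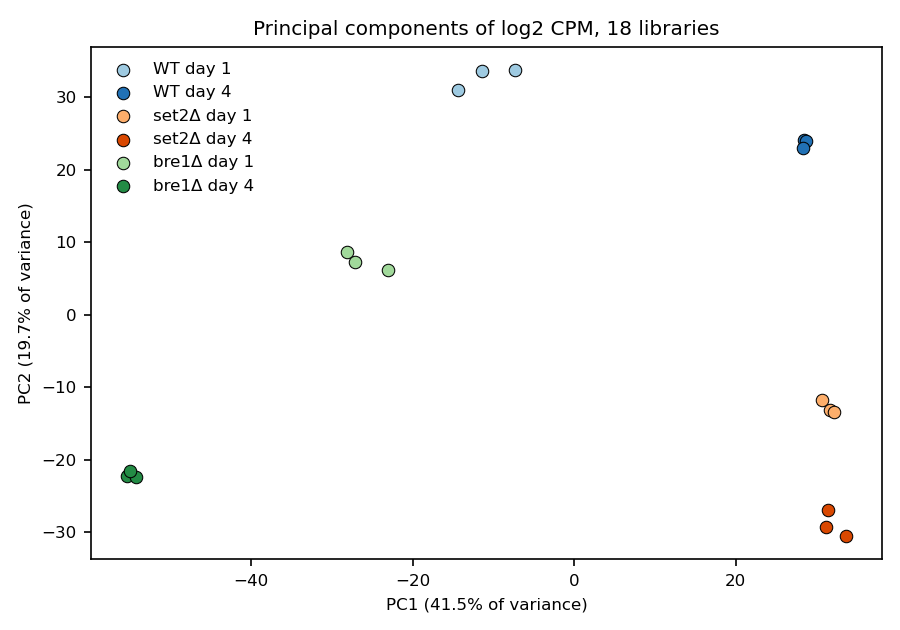
Principal components 1 and 2 of log2 CPM (arbitrary units, with the percent of variance on each axis), with each point a library and each colour a group. The 3 libraries of each of the 6 groups lie together, on axes that hold 41.5% and 19.7% of the variance.

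Between day 1 and day 4, WT cells lowered genes for the use of ethanol, acetate and fatty acids. ADH2 (YMR303C, chromosome XIII, 873291 to 874337), the alcohol dehydrogenase that oxidises ethanol, fell from 16200 ± 139 to 494 ± 28.9 CPM (-5.03 ± 0.14, adjusted p = 7.63e-18, n = 3 per group in edgeR), and the acetyl-CoA synthetase gene ACS1 fell by 2.82 ± 0.08. The first enzyme of peroxisomal fatty acid oxidation, POX1, fell by 3.97 ± 0.11, and 15 of 17 tested genes of that pathway fell (16 adjusted over the list alone). Genes of the mitochondrial respiratory chain and ribosome moved the other way: CYC1, for cytochrome c, rose by 2.56 ± 0.09, and 63 of 67 genes of the mitochondrial ribosome rose (63 adjusted over the list alone). SNZ1 (chromosome XIII, 458408 to 459301), of vitamin B6 synthesis in stationary phase, rose from 70.8 ± 3.09 to 2970 ± 52.9 CPM (5.39 ± 0.12), and the phosphate transporter gene PHO84 rose by 3.65 ± 0.09. In all, 4909 of 6320 genes were past the threshold, 2348 higher and 2561 lower at day 4, and 1191 of them changed at least 2-fold (798 higher, 393 lower).

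By camera, peroxisomal fatty acid oxidation (median -2.45, adjusted p = 7.9e-19) and the glyoxylate cycle, gluconeogenesis and acetate use (median -2.16, adjusted p = 1.6e-13) were lower than other genes, with adjusted p = 0.12 and 0.16 with an estimated correlation. MDH2 (-2.92 ± 0.08) and FBP1 (-3.42 ± 0.10) are among the latter, of which 16 of 20 fell (17 adjusted over the list alone). Mitochondrial ribosomal proteins (median 0.57, adjusted p = 2e-09) and nuclear-encoded oxidative phosphorylation (median 0.58, adjusted p = 7.1e-06) were higher, with adjusted p = 0.31 and 0.52 with an estimated correlation. Phosphate starvation genes such as VTC3 (1.34 ± 0.04) rose in 13 of 15 cases (13 adjusted over the list alone, adjusted p = 3.5e-05, and adjusted p = 0.24 with an estimated correlation). Cell wall genes such as BGL2 (2.30 ± 0.07) and the iron regulon with FRE1 (1.46 ± 0.06) were higher (adjusted p = 0.0041 and 0.017), and ergosterol genes such as HMG1 (-1.81 ± 0.05) and vacuolar hydrolases such as LAP3 (-1.66 ± 0.07) lower (adjusted p = 0.0014 and 0.0042). These 4 lists had adjusted p = 0.44 to 0.58 with an estimated correlation. Stationary-phase genes were split, with 6 that rose and 5 that fell (6 and 5 adjusted over the list alone). Their median was 0.15 and their adjusted p = 0.021, with adjusted p = 0.46 with an estimated correlation, and with the length trend removed the median was -0.12 and the adjusted p = 0.0971. Short protein-coding genes rose relative to long ones in this comparison. Spearman's rho of log2 fold change with gene length was -0.247 across 5824 genes (95% bootstrap interval -0.274 to -0.221). With the length trend removed, the median of the mitochondrial ribosomal genes was 0.42 (adjusted p = 4.2e-06) and that of the oxidative phosphorylation genes 0.36 (adjusted p = 0.0098).

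**Figure D3:**
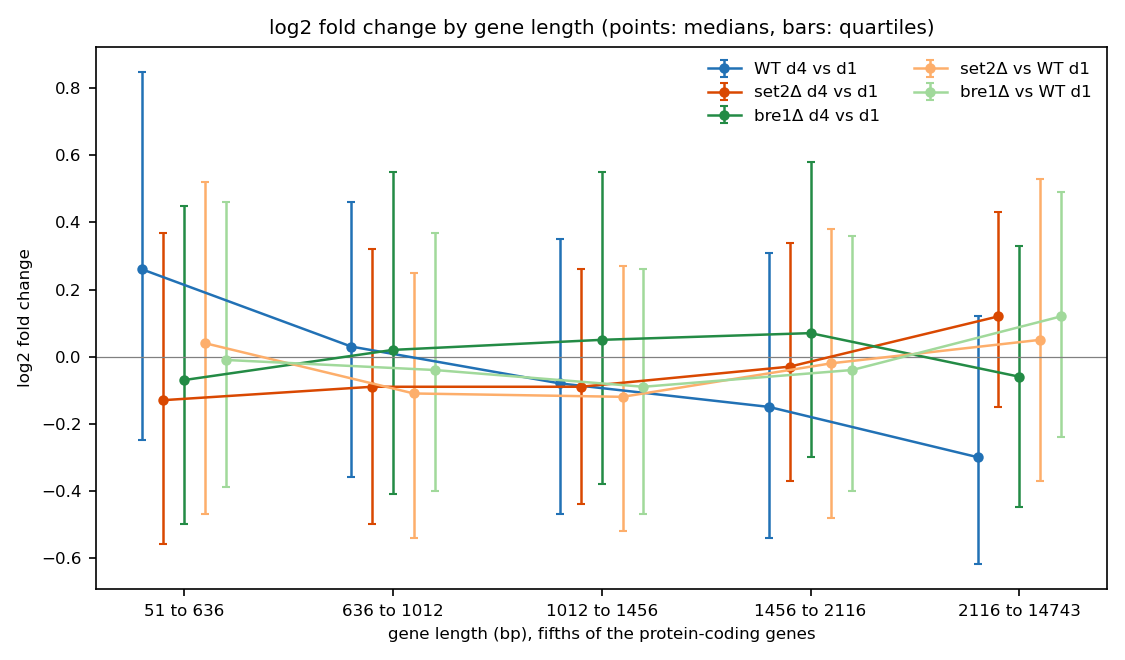
Median log2 fold change of protein-coding genes (bars, quartiles) in 5 comparisons, in 5 bins of gene length in base pairs. In WT at day 4 against day 1 the medians run from 0.26 in the shortest genes to -0.30 in the longest.

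In set2Δ cells, glycolysis genes rose between the days while respiratory genes fell. THI4 (YGR144W, chromosome VII, 780399 to 781379), for synthesis of the thiamine thiazole, rose 490-fold (8.94 ± 0.19, adjusted p = 9.68e-19, n = 3 per group in edgeR), and THI13 rose by 6.15 ± 0.17. The enolase gene ENO2 rose by 2.98 ± 0.12 and the pyruvate decarboxylase gene PDC5 by 2.71 ± 0.13, whereas CYC1 fell by 2.04 ± 0.09. Of 139 genes of the cytosolic ribosome 131 rose (131 adjusted over the list alone), as RPL31B did (2.50 ± 0.07), while the snoRNP genes NOP56 (-1.31 ± 0.05) and NOP58 (-1.83 ± 0.08) of ribosome biogenesis fell. MF(ALPHA)1, for the mating pheromone alpha factor, fell from 1350 ± 71.5 to 57.6 ± 0.757 CPM (-4.55 ± 0.09). In all, 4524 genes were past the threshold, 2168 higher and 2356 lower, and 862 changed at least 2-fold (466 higher, 396 lower). The directions depend on the scaling, with 1668 higher and 3029 lower by upper quartile (2-fold 385 and 579).

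By camera, cytosolic ribosomal protein genes were higher (median 1.23, adjusted p = 3.1e-52) and ribosome biogenesis genes lower (median -0.61, adjusted p = 2e-10), with adjusted p = 0.12 and 0.22 with an estimated correlation. Of the latter, 55 of 68 fell (55 adjusted over the list alone). Oxidative phosphorylation genes (median -0.75, adjusted p = 1.7e-09) and mitochondrial ribosomal protein genes (median -0.50, adjusted p = 1.2e-07) were lower, with adjusted p = 0.41 and 0.38 with an estimated correlation. Glycolysis and fermentation genes such as TDH2 (3.33 ± 0.11) rose in 15 of 16 cases (15 adjusted over the list alone, median 1.22, adjusted p = 1.5e-08, and adjusted p = 0.34 with an estimated correlation). Histone genes such as HHT1 (2.05 ± 0.06), autophagy genes such as ATG1 (1.57 ± 0.07) and peroxisomal fatty acid oxidation genes such as POT1 (1.84 ± 0.08) were higher (adjusted p = 3.3e-05, 7e-05 and 0.00013), with adjusted p = 0.16 to 0.44 with an estimated correlation. The phosphate starvation, stationary-phase, proteasome, and sulfur and methionine genes were higher too (adjusted p = 0.0037 to 0.023, and adjusted p = 0.39 to 0.58 with an estimated correlation), with PHO89 at 4.60 ± 0.16 and SNZ1 at 2.42 ± 0.10. The alpha-specific genes, the tricarboxylic acid cycle and the glyoxylate and gluconeogenesis genes were lower (adjusted p = 0.0033 to 0.011, and adjusted p = 0.32 to 0.63 with an estimated correlation). Within the last list FBP1 (-3.30 ± 0.10) and PCK1 (-2.52 ± 0.10) fell, while ADH2 rose by 3.27 ± 0.13. The RNA polymerase I and III subunits were lower at the edge of the threshold (adjusted p = 0.04998, and adjusted p = 0.47 with an estimated correlation) and missed it under scaling by library size only (0.0745), over protein-coding genes only (0.0587), without ribosomal protein genes in the background (0.0606) and with the length trend removed (0.0511). THI5, THI11 and THI12 also rose (8.36 ± 0.30, 4.95 ± 0.12 and 7.28 ± 0.26). They share 85.0%, 79.0% and 70.6% of their 50-base windows with other loci, so their counts depend on how shared reads were placed.

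In bre1Δ cells, genes for the separation of daughter cells, the cell wall and ribosomes rose by day 4, and stress and stationary-phase genes fell. SCW11 (YGL028C, chromosome VII, 441281 to 442909), of the glucanases that part daughter from mother, rose from 357 ± 114 to 3660 ± 205 CPM (3.36 ± 0.26, adjusted p = 2.18e-10, n = 3 per group in edgeR), and the chitinase gene CTS1 rose by 3.46 ± 0.22. The exoglucanase gene EXG1 rose by 4.02 ± 0.12 and the weak-acid exporter gene PDR12 by 4.87 ± 0.10 (adjusted p = 6.83e-19). Catalase T, CTT1, fell by 1.72 ± 0.08 and the glutamate decarboxylase gene GAD1 by 2.12 ± 0.06. Among single genes, the Ty retrotransposon genes YLR227W-B and YMR045C fell by 5.15 ± 0.19 and by 4.26 ± 0.10. In all, 4827 genes were past the threshold, 2398 higher and 2429 lower, and 1123 changed at least 2-fold (627 higher, 496 lower).

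By camera, cytosolic ribosomal protein genes (median 0.96, adjusted p = 5.8e-24) and ribosome biogenesis genes (median 0.60, adjusted p = 1.9e-07) were higher, with adjusted p = 0.3 and 0.32 with an estimated correlation. RPS28B rose by 2.67 ± 0.08 and UTP22 by 1.31 ± 0.05. Daughter cell separation genes rose in 11 of 11 cases (11 adjusted over the list alone, median 2.81, adjusted p = 6.3e-06, and adjusted p = 0.45 with an estimated correlation), DSE2 among them (3.36 ± 0.25). Cell wall genes such as SLT2 (2.14 ± 0.07), amino acid biosynthesis genes such as TRP4 (2.11 ± 0.09) and sulfur and methionine genes such as MET17 (2.19 ± 0.14) were higher (adjusted p = 2e-07, 8.7e-07 and 0.00029), with adjusted p = 0.22 to 0.31 with an estimated correlation. The general stress genes were lower (27 of 33 fell, 27 adjusted over the list alone, median -0.87, adjusted p = 1.2e-10, and adjusted p = 0.072 with an estimated correlation). So were the stationary-phase genes (10 of 13 fell, 10 adjusted over the list alone, adjusted p = 5.4e-05, and adjusted p = 0.21 with an estimated correlation), with SPG1 at -2.66 ± 0.12. Oxidative phosphorylation, proteasome and galactose genes were lower (adjusted p = 4.9e-08, 0.00022 and 0.0021, with adjusted p = 0.16 to 0.47 with an estimated correlation), as with COX13 (-1.40 ± 0.07), RPT6 (-1.21 ± 0.05) and GAL80 (-1.54 ± 0.06). Autophagy, oxidative stress defence and glyoxylate and gluconeogenesis genes were lower as well (adjusted p = 0.023 to 0.027, and adjusted p = 0.35 to 0.67 with an estimated correlation), with ATG5 at -1.50 ± 0.08 and PCK1 at -3.18 ± 0.11. The daughter-cell genes varied between the replicates of day 1, as the SD of SCW11 shows. The genes YLR227W-B and YMR045C share 97.5% and 90.8% of their 50-base windows with other loci.

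**Figure D4:**
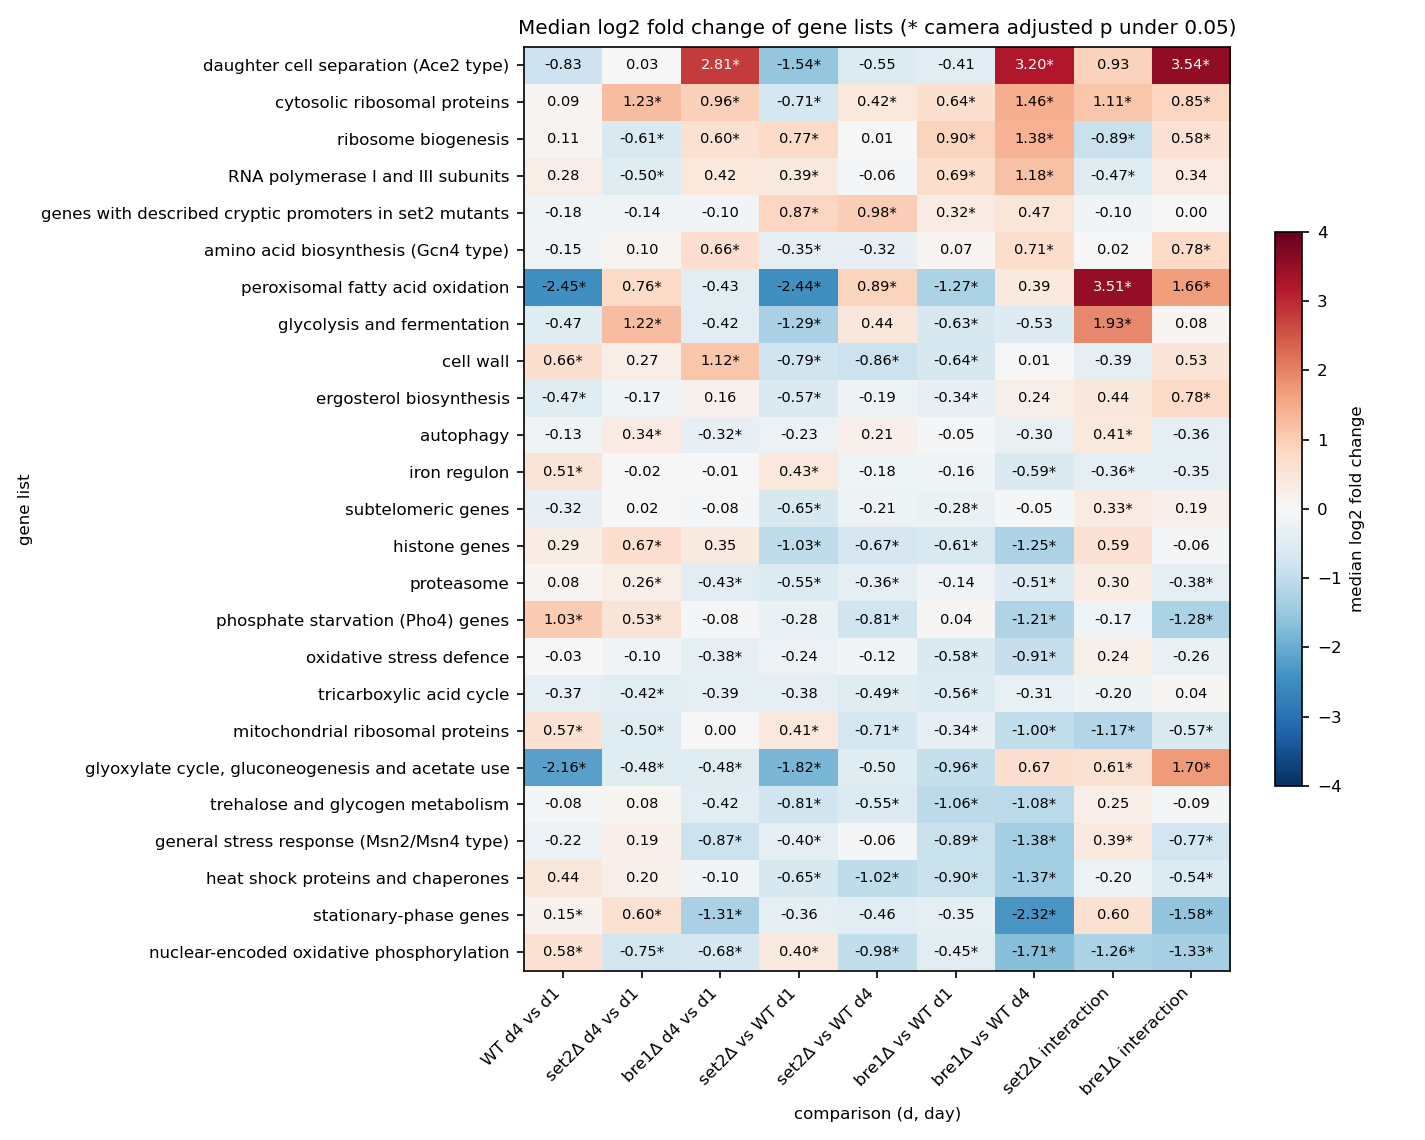
Median log2 fold change (colour) of 25 gene lists in the 9 comparisons, with an asterisk where the camera adjusted p is under 0.05. Ribosomal protein genes are highest in bre1Δ against WT at day 4 (median 1.46) and oxidative phosphorylation genes lowest in the same comparison (-1.71).

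At day 1, set2Δ cells had far less mRNA for ethanol and fatty acid use and for glycolysis than WT cells. ADH2 was at 99.9 ± 24.1 CPM against 16200 ± 139 (-7.34 ± 0.15, adjusted p = 5.15e-19, n = 3 per group in edgeR), THI4 was lower (-6.23 ± 0.17), and POX1 was lower by 3.94 on the log2 scale (-3.94 ± 0.11). All 17 tested genes of peroxisomal fatty acid oxidation and all 20 of the glyoxylate cycle and gluconeogenesis were lower (17 and 20 adjusted over the list alone). The trehalose synthesis genes TPS2 (-1.55 ± 0.05) and TPS3 (-1.55 ± 0.05) and the histone genes HTA1 (-1.77 ± 0.05) and HHF2 (-1.67 ± 0.06) were lower. SOV1, for a mitochondrial protein, was higher at 309 ± 32.7 against 40.0 ± 2.64 CPM (2.95 ± 0.12), as were CYC1 (2.58 ± 0.09) and the ribosome biogenesis gene ENP2 (2.13 ± 0.07). In all, 4890 genes were past the threshold, 2393 higher and 2497 lower, and 1207 differed at least 2-fold (654 higher, 553 lower). Under scaling by library size only 3793 were higher and 1327 lower (2-fold 1180 and 306), so the even balance rests on the TMM scaling.

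Among genes with cryptic promoters described in set2 mutants, 7 of 8 were higher and 1 lower (7 and 1 adjusted over the list alone, median 0.87, camera adjusted p = 9e-05, and adjusted p = 0.17 with an estimated correlation). SPB4 (2.24 ± 0.07), FLO8 (1.38 ± 0.06), PCA1 (193 ± 6.49 against 84.0 ± 9.04 CPM), AVO1 (0.95 ± 0.05), STE11 (0.79 ± 0.05), SYF1 (0.60 ± 0.07) and OMS1 (0.26 ± 0.07) were higher. DCP2 was lower (-0.35 ± 0.05), although it was at 0.02 under scaling by library size only. Counts over whole genes do not show where a transcript starts. By camera, peroxisomal (median -2.44, adjusted p = 1.6e-20) and glyoxylate and gluconeogenesis genes (median -1.82, adjusted p = 1.3e-14) were lower, with adjusted p = 0.11 and 0.16 with an estimated correlation. Ribosome biogenesis genes were higher (median 0.77, adjusted p = 6.6e-12) and cytosolic ribosomal protein genes lower (median -0.71, adjusted p = 4.1e-10), with adjusted p = 0.16 and 0.52 with an estimated correlation. The numbers of such genes were 57 of 68 and 113 of 139 (58 and 113 adjusted over the list alone). Trehalose and glycogen, heat shock, proteasome and histone genes were lower (adjusted p = 1.3e-07 to 1.3e-06, and adjusted p = 0.12 to 0.34 with an estimated correlation), as with the chaperone genes SIS1 (-1.94 ± 0.06) and HSP82 (-1.64 ± 0.07). Glycolysis and fermentation, subtelomeric, vacuolar hydrolase and cell wall genes were lower as well (adjusted p = 1.9e-05 to 7.3e-05, and adjusted p = 0.16 to 0.44 with an estimated correlation), as with PGK1 (-2.03 ± 0.12), CPS1 (-2.00 ± 0.07) and TIP1 (-3.04 ± 0.12).

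Further differences of set2Δ from WT at day 1 were those of ergosterol genes with ERG6 (-2.46 ± 0.08), general stress genes with HXK1 (-2.56 ± 0.08) and daughter cell separation genes with DSE1 (-2.27 ± 0.20). These 3 lists were lower (adjusted p = 0.00015 to 0.027, and adjusted p = 0.25 to 0.72 with an estimated correlation). Amino acid biosynthesis genes such as ARO4 (-1.71 ± 0.06) were lower too (median -0.35, adjusted p = 0.041, and adjusted p = 0.58 with an estimated correlation), but the list's median was 0.01 under scaling by library size only. Mitochondrial ribosomal protein, oxidative phosphorylation, iron regulon and RNA polymerase I and III genes were higher (adjusted p = 1.3e-05 to 0.033, and adjusted p = 0.44 to 0.69 with an estimated correlation), with CCC2 at 1.55 ± 0.07 and RPC82 at 1.82 ± 0.09. The RNA polymerase list missed the threshold under scaling by library size only (0.0554), and the amino acid list did so under that scaling (0.0758), over protein-coding genes only (0.0701) and with the length trend removed (0.109).

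At day 4, set2Δ cells had less mRNA for respiration, the cell wall and heat shock proteins than WT cells. UTH1 (YKR042W, chromosome XI, 519527 to 520624), of the SUN family, was at 336 ± 32.4 against 7730 ± 571 CPM (-4.53 ± 0.12, adjusted p = 6.52e-18, n = 3 per group in edgeR). CYC1 was lower (-2.02 ± 0.09), and so were COX13 (-1.58 ± 0.07) and all other tested genes of nuclear-encoded oxidative phosphorylation, 36 of 36 (36 adjusted over the list alone). The chaperone gene HSP82 (-2.35 ± 0.07) and the wall genes SCW4 (-3.12 ± 0.07) and GAS1 (-2.07 ± 0.06) were lower. SOV1 was higher at 562 ± 78.5 against 43.7 ± 4.26 CPM (3.69 ± 0.12), and so were PDC6 (4.14 ± 0.11), FLO10 (3.48 ± 0.08), APC1 (3.29 ± 0.06) and the formin gene BNR1 (3.26 ± 0.07). In all, 4972 genes were past the threshold, 2194 higher and 2778 lower, and 1383 differed at least 2-fold (616 higher, 767 lower). Under scaling by library size only the majority turned, with 2980 higher and 1933 lower (2-fold 994 and 466).

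Among genes with described cryptic promoters, 7 of 8 were again higher (7 adjusted over the list alone, median 0.98, camera adjusted p = 0.0021, and adjusted p = 0.26 with an estimated correlation). SPB4 (1.99 ± 0.07) and PCA1 (1.62 ± 0.06) led the list, and OMS1 was lower (-0.91 ± 0.07). Long genes were higher relative to short ones here (rho 0.313 with gene length). With that trend removed the list had an adjusted p of 0.052, AVO1 changed from 0.25 to -0.20, and DCP2 changed from 0.30 to -0.08. Oxidative phosphorylation (median -0.98, adjusted p = 5.9e-10) and mitochondrial ribosomal proteins (median -0.71, adjusted p = 8.4e-09) were lower than other genes by camera, with adjusted p = 0.39 and 0.34 with an estimated correlation. With the length trend removed their medians were -0.66 and -0.40. Heat shock (median -1.02, adjusted p = 2.5e-07) and cell wall genes (median -0.86, adjusted p = 2.2e-06) were lower too, with adjusted p = 0.31 and 0.36 with an estimated correlation. Phosphate starvation genes such as PHO84 (-2.89 ± 0.09), histone genes such as HHF2 (-1.84 ± 0.06) and trehalose and glycogen genes such as GPH1 (-2.98 ± 0.07) were lower (adjusted p = 0.0046 to 0.018, and adjusted p = 0.38 to 0.42 with an estimated correlation). Proteasome and tricarboxylic acid cycle genes were lower at adjusted p = 0.023 and 0.041, each with adjusted p = 0.67 with an estimated correlation. Cytosolic ribosomal protein genes (median 0.42, adjusted p = 9e-05) and peroxisomal genes (median 0.89, adjusted p = 0.002) were higher, with adjusted p = 0.69 and 0.54 with an estimated correlation. With the length trend removed the histone (0.242), proteasome (0.252) and tricarboxylic acid cycle lists (0.0625) also missed the threshold, as the latter 2 did under scaling by library size only (0.116 and 0.055). IMD2, lower in set2Δ (-4.71 ± 0.20), shares 33.7% of its 50-base windows with other loci.

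At day 1, bre1Δ cells already had more mRNA for ribosomes and less for stress defence and storage sugars than WT cells. The hexokinase gene HXK1 was at 424 ± 44.0 against 3440 ± 317 CPM (-3.02 ± 0.08, adjusted p = 1.01e-16, n = 3 per group in edgeR), CTT1 was lower (-2.30 ± 0.08), and so was CYC7, for the second isoform of cytochrome c (-3.44 ± 0.08). Glycogen phosphorylase GPH1 (-2.18 ± 0.06) and glycogen synthase GSY1 (-2.75 ± 0.09) were lower, as were the heat shock genes SSA4 (-3.33 ± 0.09) and BTN2 (-3.02 ± 0.09). Of 68 ribosome biogenesis genes 65 were higher (65 adjusted over the list alone), as RPF2 was (1.49 ± 0.06), and of 139 cytosolic ribosomal protein genes 128 were (129 adjusted over the list alone). Histone genes were lower, HTB2 by 1.54 on the log2 scale (-1.54 ± 0.05). In all, 4524 genes were past the threshold, 2263 higher and 2261 lower, and 653 differed at least 2-fold (366 higher, 287 lower). Under scaling by library size only 3606 were higher and 1214 lower (2-fold 826 and 139), so the even balance rests on the TMM scaling.

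The general stress genes were lower in 30 of 33 cases (31 adjusted over the list alone, median -0.89, adjusted p = 1.9e-17), and the trehalose and glycogen genes in 19 of 20 (19 adjusted over the list alone, median -1.06, adjusted p = 6.5e-15). Each had adjusted p = 0.028 with an estimated correlation, and they are the only 2 of the 351 tests in the 9 comparisons that were past the threshold in this way. Ribosome biogenesis (median 0.90, adjusted p = 2.4e-22), cytosolic ribosomal proteins (median 0.64, adjusted p = 1.3e-18) and RNA polymerase I and III subunits (median 0.69, adjusted p = 3.4e-06) were higher by camera. They had adjusted p = 0.072, 0.34 and 0.12 with an estimated correlation. Heat shock, peroxisomal, histone and glyoxylate and gluconeogenesis genes were lower (medians -0.90, -1.27, -0.61 and -0.96, adjusted p = 1.7e-12 to 1.8e-06, and adjusted p = 0.12 to 0.36 with an estimated correlation), as with POT1 (-1.79 ± 0.08) and ADY2 (-1.97 ± 0.09). Lower as well were oxidative stress defence, oxidative phosphorylation, tricarboxylic acid cycle and cell wall genes (adjusted p = 2.1e-06 to 0.001, and adjusted p = 0.091 to 0.63 with an estimated correlation), with FUM1 at -1.41 ± 0.07 and CWP1 at -2.63 ± 0.10.

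Further shifts in bre1Δ at day 1 were those of mitochondrial ribosomal protein genes, glycolysis and fermentation genes with ADH1 (-1.43 ± 0.09), subtelomeric genes and alpha-specific genes with MF(ALPHA)1 (-1.30 ± 0.08). These 4 lists were lower (adjusted p = 0.0033 to 0.013, and adjusted p = 0.31 to 0.65 with an estimated correlation). Ergosterol genes (adjusted p = 0.018) and nutrient signalling and lifespan regulators such as HAP4 (-1.30 ± 0.05, list median -0.29, adjusted p = 0.023) were lower, with adjusted p = 0.58 and 0.31 with an estimated correlation. The median of the second list was 0.01 under scaling by library size only, with an adjusted p of 0.116, and its adjusted p was 0.0518 with the replicate number as a block on the 6 libraries. Genes with described cryptic promoters such as SPB4 (1.06 ± 0.07) and PCA1 (0.93 ± 0.06) were higher in 6 of 8 cases (6 adjusted over the list alone, adjusted p = 0.048, and adjusted p = 0.44 with an estimated correlation), but the list had an adjusted p of 0.0864 with the length trend removed and 0.0681 with that block. The sodium pump gene ENA1, higher in bre1Δ (2.39 ± 0.07), shares 88.5% of its 50-base windows with other loci.

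At day 4, bre1Δ cells differed from WT cells in more genes than in any other of the 9 comparisons. They had more mRNA for ribosomes and daughter-cell separation, and less for respiration and stationary phase. URA1 (YKL216W, chromosome XI, 25215 to 26159), the dihydroorotate dehydrogenase of pyrimidine synthesis, was at 1010 ± 62.6 against 30.1 ± 0.799 CPM (5.06 ± 0.07, adjusted p = 2.31e-22, n = 3 per group in edgeR), SCW11 at 3660 ± 205 against 114 ± 7.99 (5.01 ± 0.28), and PDR12 was higher too (3.80 ± 0.09). The ribosomal protein genes RPS9B (2.46 ± 0.05) and RPS16B (1.85 ± 0.05) and the general amino acid permease gene GAP1 (3.58 ± 0.08) were higher. The cytochrome oxidase gene COX13 was at 397 ± 13.1 against 3665 ± 79.0 CPM (-3.21 ± 0.07), CYC1 was lower (-3.88 ± 0.10), and so were SNZ1 (-3.37 ± 0.11), ALD3 (-4.23 ± 0.09) and HSP42 (-2.89 ± 0.07). In all, 5461 genes were past the threshold, 2832 higher and 2629 lower, and 2401 differed at least 2-fold (1195 higher, 1206 lower). Under scaling by library size only 3401 were higher and 2071 lower (2-fold 1636 and 906).

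Cytosolic ribosomal protein genes were higher in 130 of 139 cases (130 adjusted over the list alone, median 1.46, camera adjusted p = 9.5e-23) and ribosome biogenesis genes such as NOP56 (1.92 ± 0.04) in 59 of 68 (59 adjusted over the list alone, adjusted p = 5.9e-15). They had adjusted p = 0.31 and 0.14 with an estimated correlation. All 11 daughter cell separation genes were higher (11 adjusted over the list alone, median 3.20, adjusted p = 0.00069, and adjusted p = 0.58 with an estimated correlation), with DSE2 at 4.72 ± 0.26. Amino acid biosynthesis genes such as ILV5 (2.86 ± 0.10), RNA polymerase genes such as RPA49 (2.37 ± 0.08) and nitrogen catabolite repressed genes such as GAT1 (3.10 ± 0.17) were higher (adjusted p = 0.0039 to 0.015, and adjusted p = 0.32 to 0.44 with an estimated correlation). Oxidative phosphorylation (median -1.71, adjusted p = 1.7e-17) and mitochondrial ribosomal protein genes (adjusted p = 6e-09) were lower, with adjusted p = 0.26 and 0.36 with an estimated correlation. General stress (median -1.38, adjusted p = 1.3e-13) and heat shock genes (median -1.37, adjusted p = 1.9e-08) were lower, with adjusted p = 0.053 and 0.26 with an estimated correlation. All 13 stationary-phase genes were lower (13 adjusted over the list alone, median -2.32, adjusted p = 2.8e-07, and adjusted p = 0.12 with an estimated correlation). Lower too were the trehalose and glycogen genes with PGM2 (-2.69 ± 0.07), proteasome genes with RPN8 (-1.87 ± 0.06), phosphate starvation genes with PHO84 (-2.92 ± 0.08), oxidative stress defence genes with GPX1 (-3.04 ± 0.07), histone genes with HHF2 (-1.64 ± 0.06) and the iron regulon with ARN2 (-2.31 ± 0.07). These 6 lists had adjusted p = 0.00014 to 0.017, and adjusted p = 0.22 to 0.52 with an estimated correlation. The histone list had an adjusted p of 0.092 with the length trend removed. PHO84 overlaps an annotated antisense RNA over 100% of its length, and the strand setting of the counting is not stated.

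The day effect differed between set2Δ and WT in 4596 genes, 2200 with a higher and 2396 with a lower day 4 to day 1 ratio in set2Δ (1627 at least 2-fold). ADH2 fell in WT and rose in set2Δ, a difference of 8.30 ± 0.19 (adjusted p = 1.18e-18, n = 3 per group in edgeR), and POX1 did so with a difference of 5.25 ± 0.15. CYC1 rose in WT and fell in set2Δ (-4.60 ± 0.12), and UTH1 likewise (-4.15 ± 0.15). THI4 rose more in set2Δ (8.48 ± 0.22). All 17 peroxisomal fatty acid genes had a higher ratio in set2Δ (17 adjusted over the list alone, median 3.51, camera adjusted p = 1.9e-25), and 66 of 67 mitochondrial ribosomal protein genes (66 adjusted over the list alone, median -1.17, adjusted p = 7.9e-19) and 35 of 36 oxidative phosphorylation genes (35 adjusted over the list alone, median -1.26, adjusted p = 8.1e-16) a lower one. They had adjusted p = 0.072, 0.14 and 0.26 with an estimated correlation. Long genes had higher ratios than short ones in set2Δ relative to WT (rho 0.279, 0.251 to 0.304). With that trend removed the medians of the mitochondrial ribosomal and oxidative phosphorylation lists were -0.93 and -1.11 (adjusted p = 8.1e-14 and 6.5e-10). Cytosolic ribosomal proteins with RPS7A (2.32 ± 0.09), glycolysis and fermentation with ENO2 (3.49 ± 0.17) and glyoxylate and gluconeogenesis genes with ACS1 (3.78 ± 0.10) had higher ratios (adjusted p = 3e-18, 2.3e-07 and 1.7e-05, with adjusted p = 0.38 to 0.41 with an estimated correlation). Subtelomeric, autophagy and general stress genes had higher ratios as well (adjusted p = 0.014 to 0.033, and adjusted p = 0.36 to 0.58 with an estimated correlation), with ATG7 at 1.42 ± 0.09 and XBP1 at 2.75 ± 0.10. Ribosome biogenesis genes such as NOP1 (-3.25 ± 0.13), RNA polymerase I and III subunits and the iron regulon had lower ratios (adjusted p = 2e-07, 0.027 and 0.042, with adjusted p = 0.31 to 0.52 with an estimated correlation). The general stress list had an adjusted p of 0.0599 over protein-coding genes only, and the iron list one of 0.0525 without ribosomal protein genes in the background.

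The day effect differed between bre1Δ and WT in 4857 genes, 2528 with a higher and 2329 with a lower ratio in bre1Δ (1898 at least 2-fold). SCW11 had a higher ratio in bre1Δ (5.36 ± 0.36, adjusted p = 2.5e-11, n = 3 per group in edgeR), with 11 of 11 daughter cell separation genes (11 adjusted over the list alone, median 3.54, camera adjusted p = 1.8e-06, and adjusted p = 0.44 with an estimated correlation). SNZ1 (-4.72 ± 0.15), SPG5 (-2.63 ± 0.09) and 12 of 13 stationary-phase genes in all (12 adjusted over the list alone, adjusted p = 1.4e-07) had lower ratios, and so did PHO84 (-3.69 ± 0.12) and COX7 (-3.21 ± 0.12), with 35 of 36 oxidative phosphorylation genes (35 adjusted over the list alone, adjusted p = 1.8e-14). The latter 2 lists had adjusted p = 0.12 and 0.3 with an estimated correlation. With the length trend (rho 0.18) removed the median of the oxidative phosphorylation list was -1.06 (adjusted p = 2.9e-09). Peroxisomal genes with POX1 (4.30 ± 0.15), cytosolic ribosomal proteins with RPS6A (1.76 ± 0.08) and glyoxylate and gluconeogenesis genes with MDH2 (3.86 ± 0.11) had higher ratios (adjusted p = 7.7e-09, 1.4e-08 and 1.9e-05, with adjusted p = 0.26 to 0.58 with an estimated correlation). Ergosterol genes with ERG11 (2.25 ± 0.12), amino acid biosynthesis genes with TRP4 (3.14 ± 0.14), nitrogen catabolite repressed genes with GAP1 (3.74 ± 0.10) and ribosome biogenesis genes did too (adjusted p = 0.0013 to 0.016, and adjusted p = 0.38 to 0.67 with an estimated correlation). Mitochondrial ribosomal proteins with RSM10 (-2.23 ± 0.07), phosphate starvation genes and general stress genes with GAD1 (-1.90 ± 0.08) had lower ratios (adjusted p = 1.2e-05 to 0.00057, and adjusted p = 0.23 to 0.44 with an estimated correlation). Proteasome and heat shock genes had lower ratios at adjusted p = 0.0041 and 0.038, with adjusted p = 0.58 and 0.67 with an estimated correlation. The ribosome biogenesis list had an adjusted p of 0.0891 with the length trend removed. RPS6A shares 45.2% of its 50-base windows with other loci.

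At day 4 many genes differed from WT in the same direction in set2Δ and in bre1Δ. CYC1, COX13 and PHO84 were lower in both, and 1467 genes were higher and 1697 lower in both, against 983 and 1156 if the calls were independent. Across genes, which are not independent replicates, Pearson's r between both sets of log2 fold changes was 0.373 and Spearman's rho 0.411. Both comparisons share the WT libraries of day 4, and 100 simulated sets of unchanged groups with shared WT libraries gave a mean r of 0.403 and at most 0.516 by that sharing alone. The same sign was found in 66.1% of genes, against 65.1% in the simulated sets. In these sets the spread between replicates made up all of the fold changes, unlike in the data. Their r and signs are therefore no measure for the observed ones. No conclusion on a shared shift of both deletions is drawn from them. The covariance, 0.444, was above the highest of the simulated ones (0.0165), and the simulated sets shared at most 1 call. The simulated groups hold only the spread between replicates. They therefore cannot tell a common effect of both deletions from a shift of the shared WT libraries. YDL218W was higher in set2Δ at 1810 ± 94.7 against 239 ± 9.12 CPM (2.92 ± 0.15) and lower in bre1Δ at 62.6 ± 3.06 CPM (-1.93 ± 0.15). COS4 was lower in set2Δ (-2.28 ± 0.40, mean 0.358 against 1.77 CPM in WT) and higher in bre1Δ (2.95 ± 0.20, mean 13.7 CPM). Its level in set2Δ lay near the floor of 3 counts, and 72.3% of its 50-base windows were found at other loci. YBR226C, a dubious reading frame, was higher in set2Δ (1.93 ± 0.21, mean 26.9 against 7.11 CPM in WT) and lower in bre1Δ (-2.22 ± 0.29, mean 1.56 CPM).

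**Figure D5:**
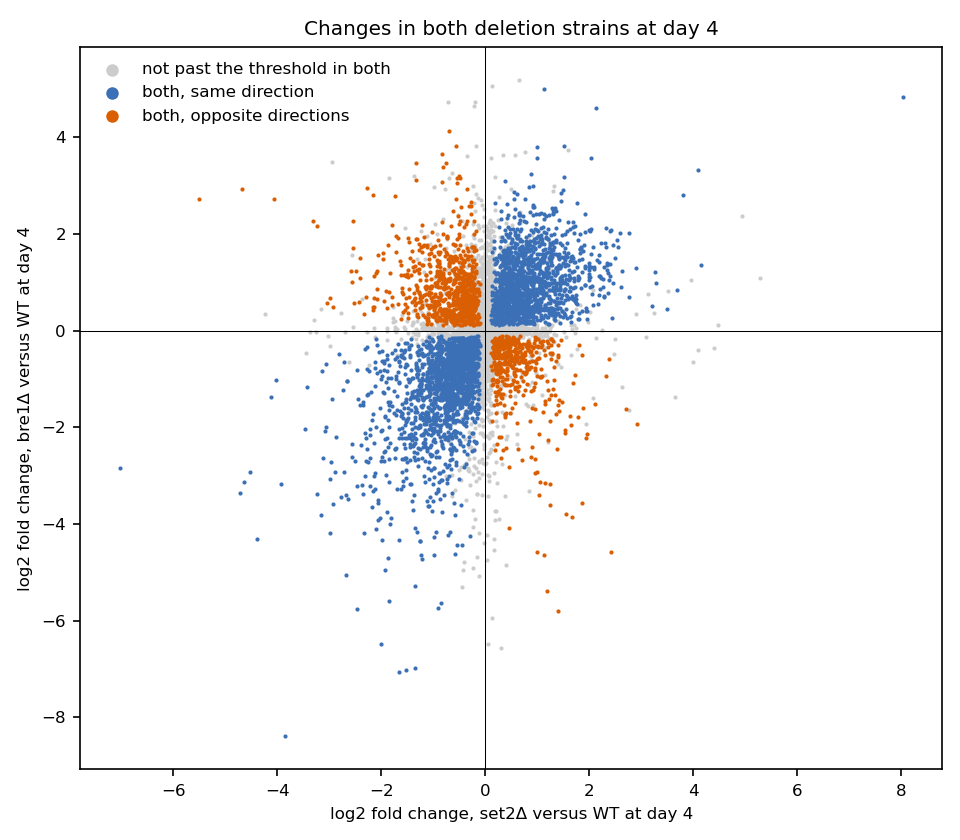
Log2 fold change against WT at day 4 in bre1Δ (vertical) and in set2Δ (horizontal), with each point a gene and with SET2 and BRE1 left out. More genes lie in the quadrants of equal sign, where 1467 were higher and 1697 lower in both deletions, than in those of opposite sign. The WT libraries of day 4 enter both axes, which alone gives more genes of equal sign.

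Age-related changes were shared in part between strains. Of the genes higher at day 4 in WT, 1035 were also higher in set2Δ (805 if independent) and 956 in bre1Δ (891), and of those lower in WT 1130 were also lower in set2Δ (955) and 1159 in bre1Δ (984). SNZ1 rose in both WT (5.39 ± 0.12) and set2Δ (2.42 ± 0.10). In bre1Δ it was at 180 ± 41.6 CPM at day 1 and 287 ± 6.66 CPM at day 4. Among changes of at least 2-fold, WT and set2Δ shared 151 rises (59 if independent) and 58 falls (25), and WT and bre1Δ shared 95 rises (79) and 82 falls (31), while 109 genes rose in WT and fell in bre1Δ (63). Across all genes r was 0.202 between WT and set2Δ and 0.019 between WT and bre1Δ, but among genes with at least 20 CPM it was 0.139 and 0.12, so r does not separate the deletions.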

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

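Of the tests below, those of BRE1 reads and of the scalings were chosen only after the result was seen.

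The day effect of set2Δ differed from that of WT by the test of the difference itself, which called 4596 genes. The median difference was -1.17 for mitochondrial ribosomal proteins, -1.26 for nuclear-encoded oxidative phosphorylation and 3.51 for peroxisomal fatty acid oxidation. Single genes with higher ratios in set2Δ were THI5 (10.36), THI12 (9.56), ADH2 (8.30), THI13 (7.96), THI11 (7.12), PDC6 (6.22) and ATO3 (5.98), and genes with lower ratios were AQR1 (-5.81), SKS1 (-4.96), CYC1 (-4.60) and UTH1 (-4.15), all as log2. Among 100 splits that exchange libraries between the strains within each day, only the real one called as many genes. The others were drawn at random from all such splits, and their median was 0 genes. The highest of them called 2562, with 1 library of each strain exchanged at day 1 and 3 at day 4. Splits that mix the strains turn their differences at each day into spread within groups. They therefore cannot exclude chance for a difference in day effects. THI5, THI11, THI12 and THI13 share most of their 50-base windows with other loci (85.0%, 79.0% and 70.6% in the first 3).

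For bre1Δ, the test of the difference called 4857 genes. The median difference was -1.33 for nuclear-encoded oxidative phosphorylation and -1.58 for stationary-phase genes. Genes with higher ratios in bre1Δ were FDH2 (5.74), SCW11 (5.36), DSE2 (5.13), ATO3 (4.62), SUN4 (4.55), FDH1 (4.51), THI12 (4.51) and DSE1 (4.50). Lower ratios were found for SNR189 (-7.01), RRT15 (-6.58), YKL068W-A (-5.92), YFR052C-A (-5.38), SNR8 (-5.26), SNR35 (-5.09) and YMR173W-A (-5.03). RRT15 varied between the replicates of bre1Δ at day 1 (148 ± 130 CPM), and YFR052C-A and YMR173W-A did not match the reference annotation. On the 12 libraries concerned, 2 of 100 splits, the real one with 4741 genes included, called as many. The other such split called 5243 genes, and it exchanged all 3 libraries of each strain at day 4 only. That exchange turns the difference between the day effects into a sum of the strain differences at both days. As for set2Δ, the splits follow the strain differences at each day. Their share therefore cannot exclude chance for a difference in day effects. SCW11, DSE1 and DSE2 varied between the replicates of day 1 in WT and bre1Δ (SCW11 455 ± 246 and 357 ± 114 CPM), and FDH1 and FDH2 share 84.2% and 84.3% of their 50-base windows with other loci.

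Short genes rose and long genes fell in WT between day 1 and day 4 (rho -0.247). Lists of short genes that moved together are argued against as the whole cause, since rho was -0.259 without all list members such as CYC1 and the ribosomal protein genes, and GC content is argued against by a partial rho of -0.238. A length bias of the libraries, by fragment size or RNA integrity, could produce such a trend, and the trend was present in each quartile of expression (the weakest at -0.182), as that explanation requires. It stays open beside a biological effect of age, which was not tested apart from it, since all WT libraries of a day share that day.

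Small nucleolar RNAs were higher in WT at day 4 than at day 1 (61 of 74 rose and 1 fell, median 1.93). Reads of host genes are argued against, since the snoRNAs outside introns had a median of 1.93 as well (66 genes). A larger share of RNA without a poly(A) tail in the day 4 than in the day 1 libraries of WT may be the cause: the other RNAs of that kind (LSR1, SCR1, NME1, RPR1, TLC1, SNR6, SNR14 and SNR19) rose in 8 of 8 cases with a median of 2.79. SnoRNAs were also higher than in WT at day 1 in set2Δ and bre1Δ of day 1 (medians 1.09 and 0.71, 51 and 41 of 74 higher), and lower than in WT at day 4 in both of day 4 (-0.64 and -1.61). Low values in WT at day 1 could thus contribute beside high ones at day 4. Whether the cells held more of these RNAs or the selection of polyadenylated RNA let more through is open. The lower ratios of SNR189, SNR8 and SNR35 in bre1Δ against WT bear on the same point, with snoRNA medians of -1.80 and -2.31 for the differences of set2Δ and bre1Δ.

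Ribosomal protein genes were higher in bre1Δ than in WT at day 4 (median 1.46, as for RPS9B at 2.46). Scaling by a few abundant genes is argued against by a median of at least 1.46 under every scaling that measures these genes, and gene length bias by a median of 1.55 with the length trend removed (95% bootstrap interval 1.43 to 1.65). BRE1 reads were at no more than 0.121% of the WT level, but this decides nothing here, since WT cells in the bre1Δ cultures would bring these genes nearer to the WT level. Within bre1Δ these genes took 4.93% to 5.35% of the counts at day 1 and 8.20% to 8.37% at day 4. Their share was also higher at day 4 than at day 1 in WT (2.9% against 2.3% to 2.7%) and in set2Δ (4.3% to 4.4% against 2.1% to 2.2%). What a later entry into stationary phase alone would do to these genes was not tested. The rise between the days therefore does not decide on it. An effect of the loss of BRE1, or a later entry as the whole or a part of the cause, stays open and was not tested further. The list was at adjusted p = 0.31 in camera with an estimated correlation.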

How the results depend on the processing

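The alternatives with the gene-length trend removed, with protein-coding genes only and with the block on 2 groups were chosen after the data had been seen. Without 1 library at a time, the genes past the threshold numbered 4749 to 4834 in WT, 4264 to 4394 in set2Δ and 4610 to 4742 in bre1Δ for day 4 against day 1. They numbered 4692 to 4780 and 4770 to 4887 for set2Δ against WT at day 1 and day 4, 4346 to 4416 and 5290 to 5427 for bre1Δ, and 4464 to 4589 and 4697 to 4839 for the differences between day effects. Under the other alternatives the totals stayed within 1.5 times the reported ones, though the counts by direction did not (lower in set2Δ and bre1Δ at day 1: 1327 and 1214 under library size only against 2497 and 2261): 4538 to 5016 in WT, 4223 to 4697 in set2Δ and 4556 to 4849 in bre1Δ by day, 4485 to 5120 and 4634 to 5058 for set2Δ against WT, 4141 to 4820 and 4998 to 5549 for bre1Δ, and 4267 to 4638 and 4511 to 4889 for the differences. With the replicate number as a block WT had 4894 such genes, and over all groups the numbers showed no pairing (mean correlation of equal numbers -0.002, with 7 of 18 libraries closest to their own number). For bre1Δ against WT at day 1, where they may pair the libraries, the block on these 6 called 4358 genes. Of the calls of named genes and lists in that comparison, this block ended those of the nutrient signalling and cryptic promoter lists only.

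Of the values of named genes, 9572 kept direction and side of the threshold, 8 lost the threshold and 5 reversed. DCP2 in set2Δ against WT at day 1 was at 0.02 under library size only and in both fits on log2 FPKM (pseudocounts 1 and 0.1), and with the length trend removed AVO1 and DCP2 in set2Δ against WT at day 4 were at -0.20 and -0.08. For DCP2 at day 1, scaling by library size, which FPKM share, moves the median of all genes from -0.01 to 0.35, about as much as DCP2 moves, and for the others the cause was not tested. SAG1 in set2Δ by day was at adjusted p = 0.063 without replicate 1 of day 1 and 0.0754 without replicate 3 of day 4, and SNR63 in bre1Δ at day 1 missed the threshold when any 1 of 4 libraries was left out, with the block on all 18 libraries (0.0576) and with the length trend removed (0.112).

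Of 137 list calls, 2 held with an estimated correlation, and fry called 307 tests, since it does not compare a list with other genes. With library size only 131 were kept, with the length trend removed 127, with protein-coding genes only 133, and 127 of 129 without ribosomal protein genes in the background. Among genes with at least 20 CPM, r between both deletions at day 4 was 0.489 and the covariance 0.48. Shared age changes of at least 2-fold numbered 151 and 58 for WT with set2Δ and 95 and 82 for WT with bre1Δ, lower counts by the added requirement. Depth limits the genes with few counts: the floor of 3 counts was 0.10 to 0.37 CPM.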

Other observations

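The tests in this part were written down before their results were seen, and the hypotheses came from the same data.

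For each of the 7 pairwise comparisons, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each of them 1 of the 10 splits, the real one, gave as many genes past the threshold, and the highest other split gave 0 by edgeR, including the other splits of bre1Δ and WT at day 1 that part every pair of equal replicate numbers. Every other split mixes both groups, which turns their difference into spread within groups. The 0 therefore cannot exclude chance, nor an effect of the replicate pairs. On the 6 libraries of each comparison, the real counts were 4703 in WT, 4642 in set2Δ and 4726 in bre1Δ for day 4 against day 1, 4654 and 5058 for set2Δ against WT at day 1 and day 4, and 4141 and 5509 for bre1Δ against WT.

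The hypothesis that set2Δ at day 1 differs from WT in the directions in which WT itself moves by day 4 was tested. ADH2 was lower in both comparisons (-7.34 and -5.03), POX1 as well (-3.94 and -3.97), and CYC1 was higher in both (2.58 and 2.56). Other genes ran the opposite way: PHO89 was lower in set2Δ at day 1 (-5.34) and rose in WT (1.93), and the cell wall list was lower in set2Δ (median -0.79) and higher in WT at day 4 (0.66). Of the genes higher in WT at day 4, 1267 were higher in set2Δ at day 1 (889 if independent), and of those lower in WT 1422 were lower in set2Δ (1012). The libraries of WT at day 1 enter both comparisons. The observed r was 0.541, with 63% of genes of the same sign. Simulated sets of unchanged groups gave a mean r of 0.527 and 67%. In those sets the spread between replicates made up all of the fold changes, unlike in the data. Their r and signs are therefore no measure for the observed ones, and no conclusion is drawn from them. The covariance of 0.542 was above the highest of 100 simulated ones (0.0327), and it was 0.532 without the members of the gene lists. The listed mitochondrial and fatty acid genes thus do not account for it. The simulated groups hold only the spread between replicates, which is too small to give this covariance. They cannot tell a shared shift from an unusual state of the shared WT libraries. Among genes with at least 20 CPM the covariance was 0.264 and r 0.402. An earlier passage of set2Δ cells into the expression state of WT at day 4 may explain a part of the shared changes but not genes such as PHO89, and an unusual state of the WT cultures at day 1, which enter both comparisons, stays open.

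The hypothesis that bre1Δ at day 1 is shifted against these directions was set to require a covariance below 0. The covariance was 0.202, above the highest simulated one (0.0329). The WT libraries of day 1 enter both comparisons and raise it, so a value above 0 cannot exclude such a shift. Among genes with at least 20 CPM the covariance was 0.063 (r 0.124). Over all genes r was 0.281, below the simulated mean of 0.542, and 53.4% of genes had the same sign (67% in the simulated sets). As for set2Δ, the simulated r and signs are no measure for these values. They decide nothing on a shift along or against these directions. The covariance exceeds the simulated ones, but for the reason given a shift against these directions is not excluded. Genes such as POT1 and ADY2 were lower in bre1Δ at day 1 (-1.79 and -1.97). The overlap was smaller than that of set2Δ, with 889 genes higher in both (841 if independent) and 1055 lower in both (916).

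Of the 39 tested lists, 8 were past the camera threshold in none of the 9 comparisons: hexose transporters, pheromone response, meiosis and sporulation, cell cycle and DNA replication, the unfolded protein response, a-specific mating genes, seripauperin, DAN and TIR genes, and chromatin factors of H2B ubiquitin and H3 methylation. A list that misses the threshold is not shown to be unchanged: TIR1 was lower in set2Δ at day 4 (-4.64 ± 0.13).

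RDN5-1, a 5S rRNA gene of a repeat, was lower in set2Δ at day 4 (-4.67 ± 0.40, mean 0.705 against 17.8 CPM in WT) and higher in bre1Δ (2.93 ± 0.18, mean 136 CPM). All of its 50-base windows occur at other loci. COX1 and COB were the 2 of 8 listed protein-coding genes of the mitochondrial genome found by name in the tables. The 4 identifiers matched to that genome, an rRNA among them, held 0.0026% to 0.0221% of the counts in any library.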
